A study of Homo sapiens with 8 samples.

How the data were processed

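RNA-seq was carried out on 8 libraries of U87MG cells, 2 untreated and 2 each after 4, 24 and 48 h of enzalutamide. Per the labels' protocols, total RNA was isolated on columns with DNase treatment and libraries were made with an Illumina kit. Per the submitters' processing notes, the reads were handled with Bowtie, and the builds hg19 and GRCh37 are named. The Bowtie version, the counting program, the gene annotation and the use of strand are not given in the sources used here. The deposited files hold whole-number counts per gene symbol, not normalised by the authors, in 1 file per library. Each file lists 23368 genes. Of these, 28 names had been turned into dates, 2 of which occurred more than once; they held 0.191 to 0.224% of the counts and were kept in the totals, and none is named in the results. Genes with near-identical copies, overlapping genes and antisense genes may share reads, because the rule for assigning reads is not known.

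Groups were taken from the labels, and libraries were numbered as in the labels. The group comparisons were 4, 24 and 48 h against control, 24 h against 4 h, and 48 h against 24 h. The tests, the gene lists, the rule for naming genes and a first set of other settings were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 14448 genes, and libraries were scaled by TMM factors of 0.870 to 1.08. All 8 libraries entered 1 quasi-likelihood fit with 1 coefficient per group, which left 4 residual degrees of freedom. The common dispersion was 0.00512, a biological coefficient of variation of 7.15%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of genes in the report come from this edgeR test. Standard errors are the absolute log2 change divided by the square root of the F statistic. Levels are CPM scaled by the TMM factors, given as mean ± SD.

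There were 39 gene lists. They covered androgen response, steroid receptors and enzymes, glioma stem cells, mitosis, G1/S and replication, DNA repair, p53 targets, the BCL2 family, the ER unfolded protein response, ATF4 targets, heat shock, NRF2 targets, hypoxia, glycolysis, oxidative phosphorylation and ribosomal proteins. Others were cholesterol and fatty acid synthesis, immediate early genes, NF-kappaB inflammation, interferon, TGF-beta and BMP, Notch, Wnt, hedgehog and YAP targets, glucocorticoid response, xenobiotic response, mesenchymal genes, extracellular matrix and replication histones. The rest were mitochondrially encoded genes and markers of neurons, oligodendrocytes, astrocytes, immune, endothelial, epithelial and erythroid cells. The 32 lists with at least 5 measured genes were tested with camera from limma 3.58.1, two-sided, with the preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2. Adjustment was over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera rests on the 4 residual degrees of freedom, so it has little power and a miss decides little.

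Named genes were the 6 largest rises and falls per time among called genes with a mean log2 CPM of at least 2 and both treated libraries on the same side of both controls; and up to 3 called members with the smallest p of each list described. The rule added the 6 genes with the largest smallest change among those called in 1 direction at all 3 times, and the 4 largest rises and falls between times. Some genes that the rule selects are not reported here.

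The other settings fixed then were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no filter (19903 genes), at least 5 CPM in at least 2 libraries (11076 genes), the replicate number as a block, fits of only the groups compared, a log2 change of at least 1, and each library left out in turn. Settings chosen after seeing the data were library totals as the only scaling, a correction for transcript length and GC content, that correction with the block, fits without the 48 h libraries, thinning of all libraries to 24620833 counts, and DESeq2 size factors for the lists. Length, GC content and exon number came from the GENCODE annotation of GRCh38 and were matched by symbol for 12773 genes (88.4%). No coordinates are given, since the builds differ. Where a fit left a group with 1 library, that library was assumed to vary like the other groups. Overlaps between comparisons that share controls were set beside 10 simulations of unchanged groups.

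The steps were tested on simulated data drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 1.5-fold. For 4 h against control, 87% and 73% of these were recovered, and 12 unchanged genes were called among 14242 tested. For 24 h the shares were 85% and 69% with 7 of 14251, and for 48 h 86% and 68% with 11 of 14262. For 24 h against 4 h they were 86% and 77% with 6 of 14257, and for 48 h against 24 h 90% and 70% with 6 of 14252. The simulated changes were few and balanced in direction, and all groups had the same spread at a given level. These shares therefore do not test the scaling or the pooled spread at 48 h, when 66.9% of tested genes were called. Replicates were compared by a chi-square test of their counts over genes with at least 10 summed counts. No library was left out of the reported fit.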

Results

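RNA was sequenced from U87MG cells, an established human glioblastoma line, that were left untreated or exposed to enzalutamide for 4, 24 or 48 h. Enzalutamide is an antiandrogen drug that is used against prostate cancer. Each of the 4 groups held 2 libraries, and the design asked how gene expression in these cells responded to the drug. Total counts were 33025426 and 32298781 in the control libraries, 24620833 and 32767660 at 4 h, 37162565 and 33105625 at 24 h, and 33793387 and 32348619 at 48 h. The labels name no vehicle and give no time for the untreated libraries, so each difference from control holds drug exposure together with anything else that differed between the dishes. The labels' extraction protocol speaks of a harvest that followed differentiation, a step that the growth and treatment protocols do not mention, so the state of the cells is uncertain. The labels also do not say whether the 2 libraries of a group came from separate cultures. The p-values of genes therefore measure only the spread between these libraries, which may be technical. Those of lists, with the preset correlation, compare the members with all other genes. They rest on the spread across genes and do not measure how well libraries agree.

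Replicate libraries correlated at Pearson's r of 0.992 to 0.995 across genes, which are not independent replicates. Their counts still differed by more than sampling noise, with a chi-square per degree of freedom of 4.50 to 20.8. The first principal component held 65.8% of the variance and set the 48 h libraries, at 88 and 79, apart from the other 6, which lay between -37.6 and -19.5. The second component held 16.9% and placed the 4 h libraries at 37.5 and 34.2 and the 24 h libraries at -31.3 and -33.

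**Figure D1:**
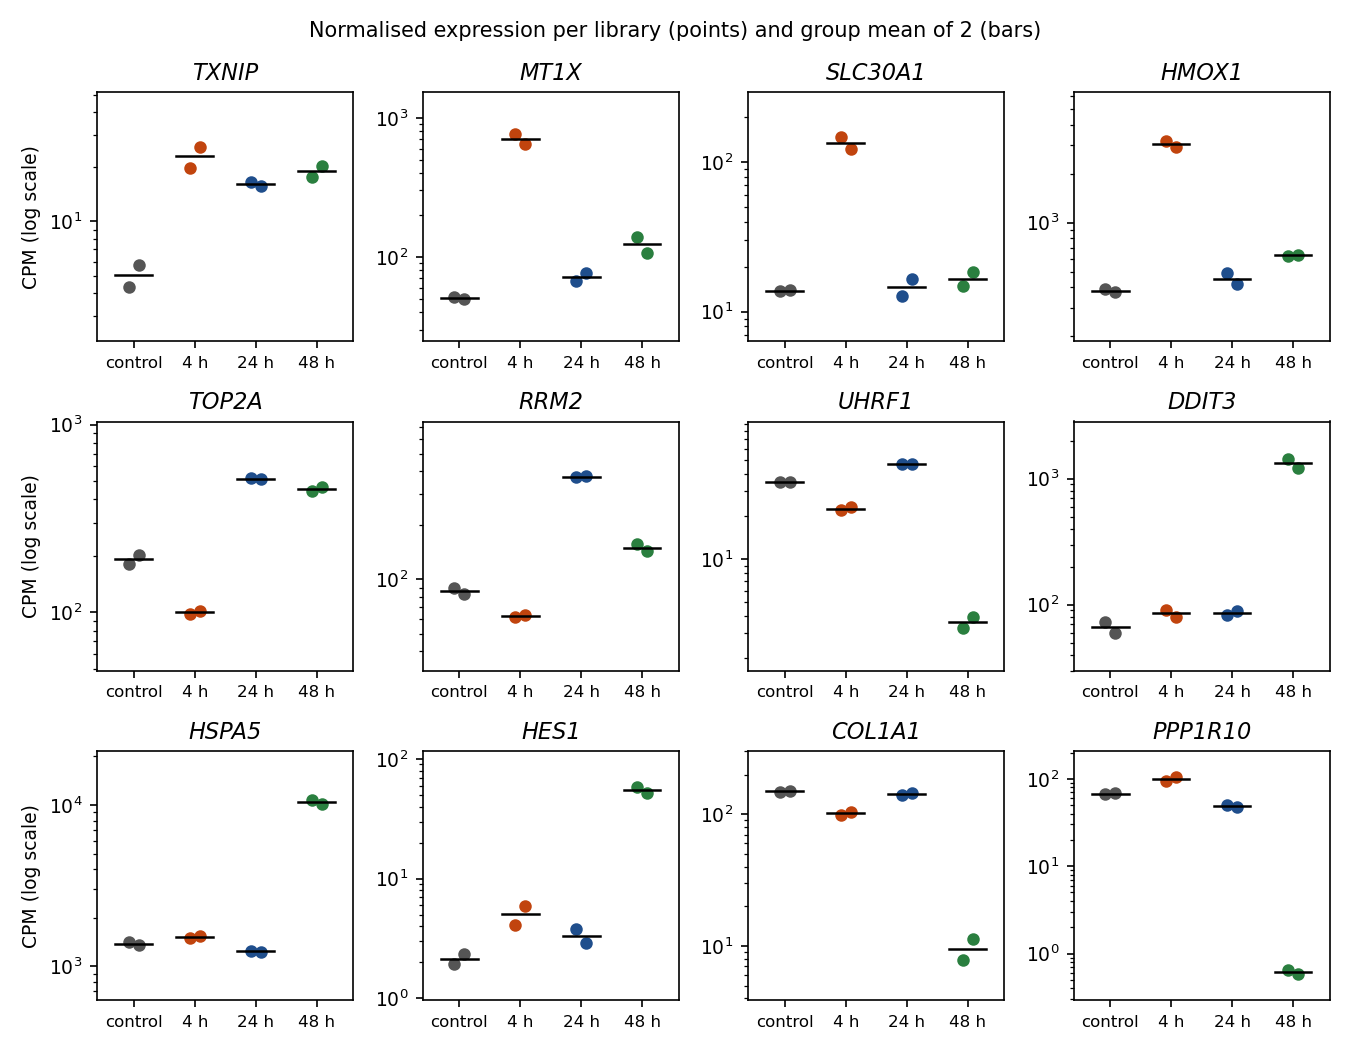
Normalised expression of 12 genes in each library, in CPM on a logarithmic axis, for control cells and for cells after 4, 24 and 48 h of enzalutamide; points are libraries and horizontal bars are means of 2. MT1X, SLC30A1 and HMOX1 peaked at 4 h, RRM2 and TOP2A at 24 h, and DDIT3, HSPA5 and HES1 at 48 h, when PPP1R10 and COL1A1 were at their lowest.

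Androgen-responsive genes moved both ways. Of 32 listed genes 22 were measured. Of these, 7 rose and 5 fell at 4 h, 7 rose and 1 fell at 24 h, and 7 rose and 7 fell at 48 h. Over all tested genes, 28.6% were called at 4 h, 22.3% at 24 h and 66.9% at 48 h, a background to the counts of every list. Adjusted over the list alone, the androgen counts were 7 and 5, 8 and 3, and 7 and 7. These splits depended on the scaling, since library totals alone gave 4 higher and 5 lower, 6 and 4, and 4 and 11 (medians 0.08, 0.10 and -0.20), and DESeq2 size factors gave 6 and 3 at 24 h. The list did not pass its test at 4 h (median log2 change 0.14, adjusted p = 0.32), at 24 h (0.16, adjusted p = 0.054) or at 48 h (0.08, adjusted p = 0.95). At 48 h the median was positive, the mean was -0.23 and the test pointed down. The 24 h result passed the threshold without control replicate 2 (adjusted p = 0.020) and with scaling by library totals (adjusted p = 0.043). PMEPA1, a target of both androgen and TGF-beta signalling, rose at 4 h (log2 change 2.59, SE 0.09) and fell at 48 h (log2 change -1.89, SE 0.10). TPD52 rose at 24 h (log2 change 0.64, SE 0.07). SLC45A3 was lower at 48 h (log2 change -3.24, SE 0.35).

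After 4 h of enzalutamide, MT1X, SLC30A1 and HMOX1 rose, and genes of cell division were lower as a group. MT1X, a metallothionein that binds zinc and other metals, rose from 50.5 ± 1.38 to 710 ± 80.2 CPM (mean ± SD, n = 2 libraries, as for every group mean that follows), 14.1-fold (log2 change 3.81, SE 0.13, adjusted p = 2.4e-08). SLC30A1, the zinc exporter of the plasma membrane, rose 9.79-fold, from 13.8 ± 0.127 to 135 ± 16.8 CPM (log2 change 3.29, SE 0.14, adjusted p = 8.6e-08). HMOX1, which encodes haem oxygenase, rose 8.04-fold, from 380 ± 10.8 to 3054 ± 198 CPM (log2 change 3.01, SE 0.08, adjusted p = 5.74e-09). All 32 measured genes of the mitosis list fell, by a median of 2-fold (32 adjusted over the list alone). That list passed its test with adjusted p = 3.4e-29, and had adjusted p = 0.18 with an estimated correlation.

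The metallothionein genes MT1G, MT1M and MT1F were also among the largest rises at 4 h, from low levels, MT1G by 7.15 (SE 0.32), MT1M by 5.85 (SE 0.25) and MT1F by 3.13 (SE 0.15) on the log2 scale. These genes and MT1X are near-identical copies whose reads can be assigned to the wrong member, so the value of each, MT1X included, is uncertain. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 13.4-fold (log2 change 3.74, SE 0.10). The largest falls were those of E2F2 (log2 change -1.92, SE 0.22), the pentraxin gene PTX3 (-1.87, SE 0.07), LRRN3 (-1.75, SE 0.14), the interferon-induced gene IFI44L (-1.71, SE 0.14), PLCL2 (-1.67, SE 0.14) and RMI2 (-1.57, SE 0.18).

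In the mitosis list, ANLN (log2 change -1.19, SE 0.08), PLK1 (-1.12, SE 0.08) and BUB1 (-1.10, SE 0.08) had the smallest p. Of 30 genes of DNA replication and the G1/S transition, 25 fell and none rose (25 lower and 1 higher adjusted over the list alone, median log2 change -0.56, adjusted p = 7.2e-12, and adjusted p = 0.18 with an estimated correlation). They included the helicase genes MCM3 (-0.69, SE 0.07) and MCM2 (-0.55, SE 0.06). DNA repair genes fell in 18 of 22 cases (19 adjusted over the list alone, median log2 change -0.49, adjusted p = 1.2e-08, and adjusted p = 0.18 with an estimated correlation), among them BLM (-0.79, SE 0.12).

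Several stress and signalling lists rose at 4 h. Among immediate early genes 13 of 18 rose and none fell (14 higher and 1 lower adjusted over the list alone, median log2 change 0.64, adjusted p = 1.3e-06, and adjusted p = 0.16 with an estimated correlation), with FOSB at 3.01 (SE 0.22) and DUSP1 at 0.88 (SE 0.07). Targets of TGF-beta and BMP signalling rose in 11 of 14 cases and fell in 2 (11 and 2 adjusted over the list alone, median 0.90, adjusted p = 2e-06, and adjusted p = 0.18 with an estimated correlation), including PMEPA1 and SKIL (1.68, SE 0.14). Heat shock genes rose in 10 of 14 cases (11 adjusted over the list alone, median 0.38, adjusted p = 2.6e-07, and adjusted p = 0.31 with an estimated correlation). HSPH1 rose by 1.07 (SE 0.07) on the log2 scale, and the near-identical pair HSPA1A and HSPA1B, whose reads cannot be told apart with certainty, by 1.84 (SE 0.10) and 1.83 (SE 0.10). Hypoxia genes rose in 12 of 20 cases and fell in 2 (12 and 2 adjusted over the list alone, median 0.33, adjusted p = 8.2e-06, and adjusted p = 0.20 with an estimated correlation), among them VEGFA (1.59, SE 0.07) and BHLHE40 (1.77, SE 0.08).

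Smaller shifts at 4 h passed the list test in metabolism. Glycolysis genes rose in 9 of 21 cases (9 adjusted over the list alone, median 0.12, adjusted p = 0.0045, and adjusted p = 0.63 with an estimated correlation), with PFKFB3 at 1.29 (SE 0.13) and SLC2A1 at 0.98 (SE 0.10). Cholesterol synthesis genes rose in 10 of 23 cases (12 adjusted over the list alone, median 0.21, adjusted p = 0.0051, and adjusted p = 0.18 with an estimated correlation), including INSIG1 (1.32, SE 0.07). NRF2 targets rose in 7 of 19 cases and fell in 1 (9 and 3 adjusted over the list alone, median 0.21, adjusted p = 0.023, and adjusted p = 0.18 with an estimated correlation). HMOX1, OSGIN1 (1.01, SE 0.07) and SRXN1 (0.84, SE 0.06) led them, and the list missed the threshold without control replicate 2 (adjusted p = 0.057). Glucocorticoid-responsive genes rose in 9 of 15 cases and fell in 4 (9 and 4 adjusted over the list alone, median 0.43, adjusted p = 0.020, and adjusted p = 0.23 with an estimated correlation); MT1X, ANGPTL4 and DUSP1, which led this list, also respond to other signals. Interferon-responsive genes went the other way, with 5 of 21 lower and 1 higher (10 and 1 adjusted over the list alone, median -0.26, adjusted p = 0.0024, and adjusted p = 0.18 with an estimated correlation), including IFI44 (-1.23, SE 0.11) and OAS3 (-1.48, SE 0.16). Scaled by library totals alone, 8 glycolysis genes were higher and 2 lower (median 0.06), 7 and 3 NRF2 targets (median 0.14), and 1 and 10 interferon-responsive genes, and with transcript length and GC content corrected 9 and 3, 9 and 2, and 1 and 9.

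Across all 14448 tested genes, 2163 were higher and 1964 lower at 4 h than in control by edgeR's quasi-likelihood test, 353 and 236 of them by at least 2-fold. With library totals as the only scaling the split was 1652 higher and 2667 lower, or 38.2% higher against 52.4%. Leaving out any of the 4 libraries compared brought the counts to between 1207 and 1286 higher and between 986 and 1180 lower.

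**Figure D2:**
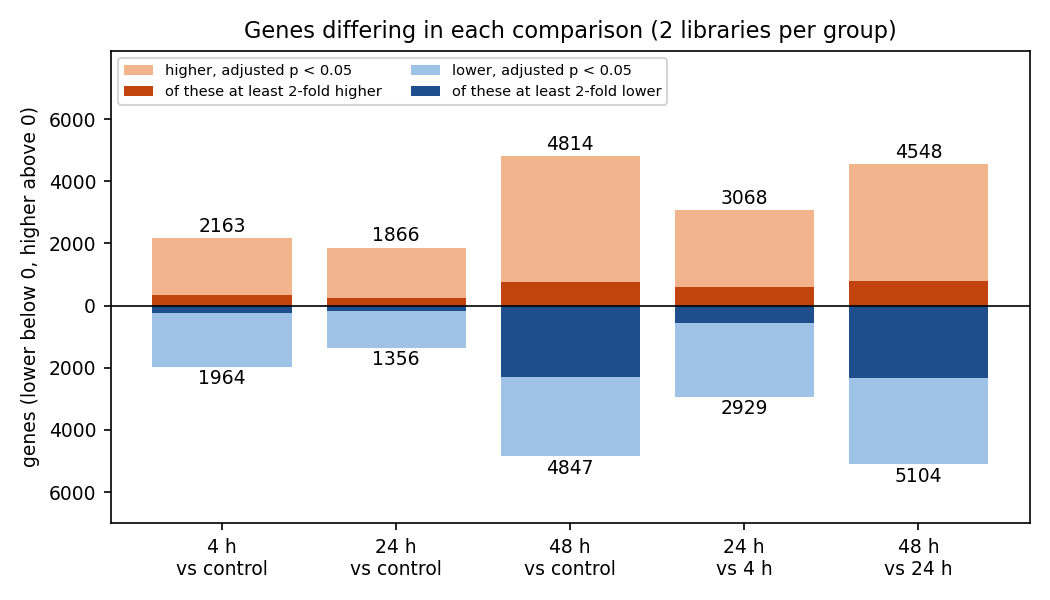
Number of genes with adjusted p under 0.05 in each of 5 comparisons, with genes higher in the group named first above 0 and lower genes below 0; the darker part of each bar is the genes that differed by at least 2-fold. At 48 h, 2290 genes were at least 2-fold lower and 766 at least 2-fold higher than control.

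At 24 h the direction of the cell division genes was the opposite of that at 4 h. RRM2, the small subunit of ribonucleotide reductase, rose 4.34-fold, from 86.0 ± 4.88 to 373 ± 5.98 CPM (log2 change 2.12, SE 0.07, adjusted p = 7e-08). TOP2A, the topoisomerase of dividing cells, rose 2.68-fold, from 192 ± 15.3 to 515 ± 6.01 CPM (log2 change 1.42, SE 0.07, adjusted p = 9.83e-07). In the mitosis list 31 of 32 genes rose and none fell (32 higher adjusted over the list alone, median log2 change 1.03). It passed its test with adjusted p = 1.5e-30, and had adjusted p = 0.18 with an estimated correlation. STRA6, the receptor for retinol-binding protein, rose 11.6-fold, from 1.60 ± 0.104 to 18.6 ± 1.06 CPM (log2 change 3.53, SE 0.18, adjusted p = 1.19e-06).

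Replication and G1/S genes rose in 27 of 30 cases at 24 h (28 adjusted over the list alone, median log2 change 0.74, adjusted p = 5.6e-19, and adjusted p = 0.18 with an estimated correlation), including RRM1 (0.94, SE 0.07). KIF11 (1.47, SE 0.08) and ANLN (1.25, SE 0.07) rose in the mitosis list. DNA repair genes rose in 18 of 22 cases (19 adjusted over the list alone, median 0.93, adjusted p = 6.6e-14, and adjusted p = 0.18 with an estimated correlation), with FANCD2 at 1.34 (SE 0.11) and FANCI at 1.12 (SE 0.07). Targets of p53 rose in 13 of 24 cases and none fell (13 adjusted over the list alone, median 0.43, adjusted p = 3.7e-07, and adjusted p = 0.18 with an estimated correlation). Among them were CDKN1A, an inhibitor of cyclin-dependent kinases (0.63, SE 0.07), GDF15 (1.00, SE 0.11) and BTG2 (1.74, SE 0.20).

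Glycolysis genes rose in 15 of 21 cases and fell in 1 at 24 h (15 and 2 adjusted over the list alone, median 0.35, adjusted p = 5.5e-06, and adjusted p = 0.44 with an estimated correlation). Hypoxia genes, which share members with them, rose in 12 of 20 cases and fell in 4 (12 and 5 adjusted over the list alone, median 0.28, adjusted p = 0.0048, and adjusted p = 0.41 with an estimated correlation). LDHA (0.87, SE 0.06), ALDOC (1.00, SE 0.07) and PGK1 (0.79, SE 0.06) rose and belonged to both lists, and BNIP3 (0.96, SE 0.07) rose in the hypoxia list. Inflammatory targets of NF-kappaB fell in 12 of 22 cases and rose in 3 (12 and 4 adjusted over the list alone, median -0.27, adjusted p = 0.0027, and adjusted p = 0.30 with an estimated correlation), among them the chemokine genes CXCL3 (-1.06, SE 0.09) and CXCL1 (-0.96, SE 0.11) and the superoxide dismutase gene SOD2 (-0.71, SE 0.07). Immediate early genes rose in 8 of 18 cases and fell in 2 (10 and 2 adjusted over the list alone, median 0.26, adjusted p = 0.020, and adjusted p = 0.26 with an estimated correlation), including EGR1 (1.11, SE 0.12). With transcript length and GC content corrected, 5 of the NF-kappaB targets were higher and 10 lower.

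Calls for a further pair of lists at 24 h rested on single libraries. ATF4 targets of the integrated stress response fell in 9 of 27 cases and rose in 1 (10 and 2 adjusted over the list alone, median -0.14, adjusted p = 0.014, and adjusted p = 0.66 with an estimated correlation), with AARS at -0.45 (SE 0.06). Their adjusted p was 0.35 without control replicate 1 and 0.085 without 24 h replicate 1. TGF-beta and BMP targets rose in 6 of 14 cases (8 higher and 1 lower adjusted over the list alone, median 0.23, adjusted p = 0.035, and adjusted p = 0.46 with an estimated correlation), with ID1 at 0.68 (SE 0.09). Their adjusted p was 0.052 without control replicate 1 and 0.055 without 24 h replicate 1. The TGF-beta and BMP counts were 3 higher and 1 lower with library totals alone and 4 and 1 with DESeq2 size factors, and the ATF4 counts were 1 and 11 (median -0.21) with library totals and 3 and 10 with transcript length and GC content corrected.

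Metallothionein genes MT1G (log2 change 5.95, SE 0.33), MT1M (4.21, SE 0.26) and MT1F (2.07, SE 0.15) remained among the largest rises at 24 h, with the same uncertainty over shared reads, and EFHC2 rose by 2.17 (SE 0.10). The largest falls were in LTF, which encodes lactoferrin (log2 change -2.85, SE 0.24), the hyaluronan synthase gene HAS3 (-2.05, SE 0.16), LRRC32 (-1.96, SE 0.15), the urea transporter gene SLC14A1 (-1.93, SE 0.19), LSAMP (-1.80, SE 0.14) and DIRC3 (-1.65, SE 0.18).

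In total 1866 genes were higher and 1356 lower at 24 h than in control, 244 and 171 of them by at least 2-fold. With library totals as the only scaling the split was 1359 higher and 1921 lower, or 41.4% higher against 57.9%. The counts fell to between 843 and 1058 higher and between 489 and 608 lower when any of the 4 libraries compared was left out, and were 2878 or 2879 higher and 2074 or 2075 lower without 48 h replicate 1 or 2.

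At 48 h the changes were wider, with a rise of genes of endoplasmic reticulum (ER) stress and a fall of genes of the extracellular matrix. HSPA5, the main chaperone of the ER, rose 7.57-fold, from 1386 ± 31.1 to 10500 ± 420 CPM (log2 change 2.92, SE 0.06, adjusted p = 6.95e-11). DDIT3, the stress-induced transcription factor CHOP, rose 19.9-fold, from 66.4 ± 9.10 to 1321 ± 138 CPM (log2 change 4.31, SE 0.12, adjusted p = 4.55e-10). COL1A1, a chain of type I collagen, fell 15.8-fold, from 149 ± 2.00 to 9.48 ± 2.44 CPM (log2 change -3.98, SE 0.12, adjusted p = 1.17e-09). All 40 measured ribosomal protein genes rose, by a median of 0.61 on the log2 scale (40 adjusted over the list alone). That list passed its test with adjusted p = 4.8e-10, and had adjusted p = 0.53 with an estimated correlation. The test did not match genes on level, and the highest of 10 equal groups of genes by level had a median of 0.35.

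Genes of the ER unfolded protein response rose in 16 of 18 cases and fell in 1 at 48 h (16 and 1 adjusted over the list alone, median log2 change 0.58, adjusted p = 1.7e-05, and adjusted p = 0.45 with an estimated correlation), including HERPUD1 (2.42, SE 0.08) and XBP1 (1.79, SE 0.07). ATF4 targets rose in 17 of 27 cases and fell in 7 (17 and 7 adjusted over the list alone, median 0.68, adjusted p = 0.0057, and adjusted p = 0.59 with an estimated correlation). DDIT3, ATF3 (3.93, SE 0.08) and SLC3A2, the heavy chain of amino acid transporters (2.63, SE 0.09), led them. PPP1R15A, which directs dephosphorylation of the translation factor eIF2-alpha, rose by 3.32 (SE 0.09). Targets of p53 rose in 13 of 24 cases and fell in 4 (14 and 4 adjusted over the list alone, median 0.41, adjusted p = 0.010, and adjusted p = 0.45 with an estimated correlation), with GDF15 at 3.18 (SE 0.11), GADD45A at 2.40 (SE 0.09) and CDKN1A at 1.44 (SE 0.07). The p53 list missed the threshold without 48 h replicate 2 (adjusted p = 0.053). Scaled by library totals alone, 11 p53 targets were higher and 6 lower (median 0.13), 15 and 9 ATF4 targets (median 0.40), and 11 and 2 genes of the unfolded protein response (median 0.30).

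Mitosis genes were higher at 48 h in 25 of 32 cases and lower in 2 (26 and 2 adjusted over the list alone, median 0.55, adjusted p = 1.6e-06, and adjusted p = 0.45 with an estimated correlation), among them PLK1 (1.65, SE 0.07), TPX2 (1.40, SE 0.07) and TOP2A (1.24, SE 0.07). Of the replication and G1/S genes 17 of 30 fell and 9 rose (17 and 11 adjusted over the list alone), and the list did not pass its test (median -0.31, adjusted p = 0.14). UHRF1, a factor that maintains DNA methylation (-3.28, SE 0.11), the cyclin gene CCNE2 (-3.75, SE 0.16) and MCM6 (-1.71, SE 0.07) were among the lower members. DNA repair genes fell in 11 of 22 cases and rose in 8 (11 and 8 adjusted over the list alone), without passing the list test (median -0.28, adjusted p = 0.32), and PARP1 fell by 1.07 (SE 0.06) on the log2 scale. Under scaling by library totals alone, 18 mitosis genes were higher and 3 lower (median 0.27), 8 and 18 replication and G1/S genes (median -0.59), and 0 and 12 DNA repair genes (median -0.56). Differences between these lists were not tested.

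Oxidative phosphorylation genes rose in 26 of 31 cases and fell in 1 at 48 h (26 and 1 adjusted over the list alone, median 0.43, adjusted p = 8.9e-05, and adjusted p = 0.59 with an estimated correlation), with SDHB at 0.70 (SE 0.07). Scaling by library totals moved the median of all genes by -0.278. It left 35 of the 40 ribosomal protein genes higher and none lower (median 0.33), and 11 oxidative phosphorylation genes higher and 3 lower (median 0.15). With transcript length and GC content corrected, these medians were 0.36 and 0.20. Across all genes the 48 h change went with the level of expression, from a median of -0.63 in the lowest of 10 equal groups by level to 0.35 in the highest. The list tests did not match genes on level, so part of the rise of the ribosomal protein and oxidative phosphorylation lists may go with level. Extracellular matrix genes fell in 14 of 21 cases and rose in 2 (14 and 2 adjusted over the list alone, median -0.52, adjusted p = 0.0069, and adjusted p = 0.45 with an estimated correlation), with COL1A2 at -3.98 (SE 0.13) and COL5A1 at -1.85 (SE 0.07). TGF-beta and BMP targets fell in 9 of 14 cases and rose in 2 (9 and 2 adjusted over the list alone, median -0.56, adjusted p = 0.021, and adjusted p = 0.45 with an estimated correlation), including ID1 (-2.90, SE 0.10) and the inhibitory Smad gene SMAD6 (-5.17, SE 0.25). The matrix list had a median of -0.80 with library totals as the only scaling.

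Among single genes, HES1, a transcriptional repressor induced by Notch, rose 25.8-fold at 48 h, from 2.14 ± 0.306 to 55.3 ± 4.20 CPM (log2 change 4.69, SE 0.18). GPRC5B rose by 4.03 (SE 0.19). HEATR8-TTC4, a read-through transcript that shares exons with neighbouring genes, was counted 3.38 higher on the log2 scale (SE 0.16), a value that is uncertain for that reason. PPP1R10, a nuclear regulator of protein phosphatase 1, fell 109-fold, from 67.8 ± 1.09 to 0.616 ± 0.0440 CPM (log2 change -6.77, SE 0.13). DGCR8, the partner of Drosha in microRNA processing, fell 42-fold (log2 change -5.39, SE 0.14). Large falls were also seen for GPR39, a zinc-sensing receptor (-5.45, SE 0.30), FAM212B (-5.02, SE 0.12) and PRMT6, an arginine methyltransferase (-4.87, SE 0.17).

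Of all tested genes 4814 were higher and 4847 lower at 48 h than in control, 766 and 2290 of them by at least 2-fold. With library totals as the only scaling the split was 2742 higher and 6729 lower, or 29% higher against 49.8%, with 408 and 3185 of them at least 2-fold.

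**Figure D3:**
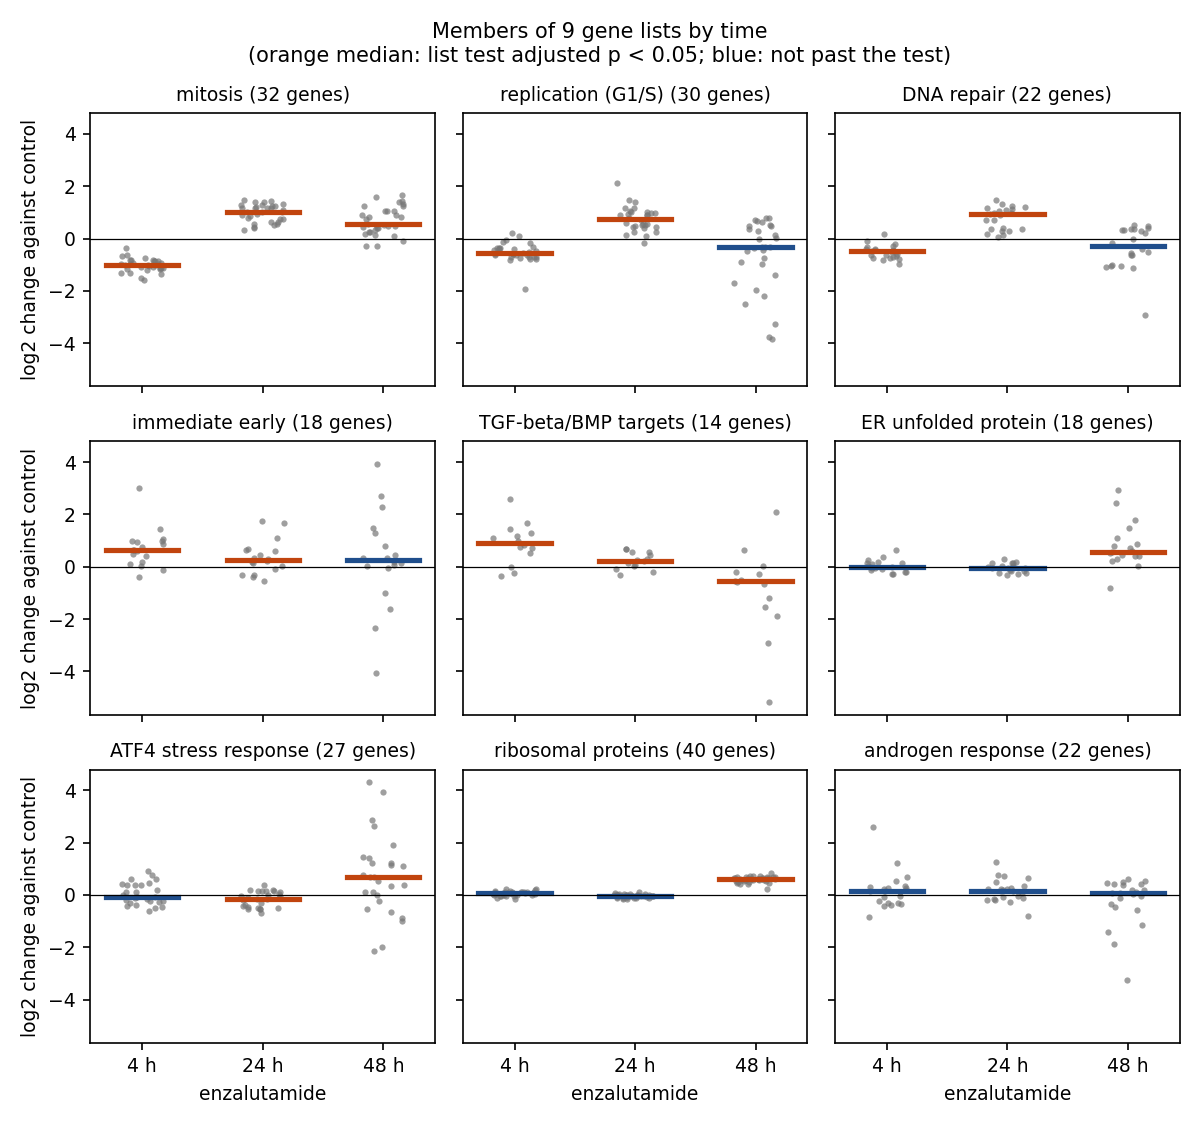
Log2 change against control of every measured member of 9 gene lists after 4, 24 and 48 h of enzalutamide; each point is a gene and each horizontal bar the median of the list, in orange where the list passed its test with the preset correlation and in blue where it did not. The mitosis list fell by a median of 2-fold at 4 h, and its median log2 change was 1.03 at 24 h and 0.55 at 48 h.

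The treated times were also compared with each other, in the same fit of all 8 libraries. Between 4 h and 24 h all 32 mitosis genes rose (32 adjusted over the list alone, median log2 difference 2.11, adjusted p = 4.1e-32, and adjusted p = 0.17 with an estimated correlation). Replication and G1/S genes rose in 28 of 30 cases (28 adjusted over the list alone, median 1.24, adjusted p = 1.5e-19, and adjusted p = 0.17 with an estimated correlation) and DNA repair genes in 21 of 22 (21 adjusted over the list alone, median 1.49, adjusted p = 2.5e-14, and adjusted p = 0.17 with an estimated correlation). E2F2 (3.39, SE 0.21), E2F8 (3.17, SE 0.17), the kinetochore gene SPC24 (2.86, SE 0.19) and AURKB (2.83, SE 0.12) rose most, while ANGPTL4 (-3.40, SE 0.10), MT1X (-3.31, SE 0.13), SLC30A1 (-3.21, SE 0.14) and KRTAP1-5 (-3.09, SE 0.24) fell most. KRTAP1-5 and MT1X belong to families of similar genes, so their values are uncertain. In all 5997 genes differed, 3068 higher and 2929 lower at 24 h (2848 and 3150 with DESeq2 size factors), and 3823 differed without 24 h replicate 2.

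Between 24 h and 48 h, LTF rose most (log2 difference 5.87, SE 0.20), followed by GPRC5B (4.25, SE 0.19), HES1 (4.04, SE 0.17) and DDIT3 (3.95, SE 0.11). PPP1R10 (-6.30, SE 0.13), E2F2 (-5.31, SE 0.26), SMAD6 (-5.10, SE 0.25) and ANGPTL4 (-4.83, SE 0.18) fell most. Replication and G1/S genes fell in 26 of 30 cases and rose in 1 (26 and 1 adjusted over the list alone, median -0.95, adjusted p = 4.8e-08, and adjusted p = 0.50 with an estimated correlation). The ER unfolded protein response list rose in 17 of 18 cases and fell in 1 (17 and 1 adjusted over the list alone, median 0.77, adjusted p = 1.8e-06, and adjusted p = 0.47 with an estimated correlation). Of 9652 differing genes 4548 were higher and 5104 lower at 48 h, and with library totals as the only scaling 3088 were higher and 6532 lower, or 32.1% against 47.1%.

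A total of 185 genes were higher and 178 lower than control at all 3 times. TXNIP, a thioredoxin-binding regulator of glucose uptake, rose by 2.18 (SE 0.16), 1.67 (SE 0.16) and 1.90 (SE 0.17) on the log2 scale at 4, 24 and 48 h. SERPIND1, which encodes heparin cofactor II, rose by 2.04 (SE 0.16), 1.99 (SE 0.16) and 1.74 (SE 0.16). RNF144B, a ubiquitin ligase gene, had log2 changes of -2.12 (SE 0.23), -1.75 (SE 0.21) and -3.69 (SE 0.27). MT1G rose at all 3 times as well, by 2.46 (SE 0.44) at 48 h. HAND2, selected by the same rule, was close to the detection limit in control cells, at 0.443 ± 0.0249 CPM. The 24 h call of HAND2 was lost without control replicate 1 (adjusted p = 0.0557), control replicate 2 (0.0609) or 24 h replicate 1 (0.112).

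Genes higher at both 4 h and 24 h numbered 400, where independent lists would share 279 and unchanged groups simulated against the same controls shared 0.1 on average. For lower genes the numbers were 321, 184 and 0. Between 24 h and 48 h, 870 higher genes and 698 lower genes were shared, against 622 and 455 for independent lists and 0 in the simulations. Between 4 h and 48 h, 780 and 806 were shared, against 721 and 659. The log2 changes at 24 h and 48 h had a covariance of 0.123 across genes, against 0.0267 simulated (r 0.277 against 0.493), those at 4 h and 24 h 0.0369 against 0.0267 (r 0.163 against 0.496), and those at 4 h and 48 h 0.0280 against 0.0268 (r 0.0550 against 0.472). The simulated groups held no changed genes, so almost none were called. Their shared counts therefore cannot show how much of the overlap comes from the shared controls. The 2 control libraries were not split, which would have left each comparison with 1 control. Part of the excess may therefore come from the shared controls. For 4 h and 48 h the covariance exceeded the simulated one by only 0.0012. Shared and opposite changes can cancel in a covariance, and the simulations gave each gene 1 spread for all groups. This value therefore does not decide what lay beyond the shared controls. Of the genes lower at 4 h, 514 were higher at 24 h, where independent lists would give 254, and of those higher at 4 h, 197 were lower at 24 h, against 203. For 24 h and 48 h, 359 genes went from lower to higher, against 452, and 493 from higher to lower, against 626. For 4 h and 48 h the numbers were 681 against 654 and 812 against 726. For these 2 times, then, shared and opposite genes both exceeded independent lists.

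Glioma stem cell genes, which the title of the series brings in, moved both ways. Of 28 listed genes 20 were measured; SOX2, PROM1, POU5F1 and NANOG were below the filter on low counts. At 4 h 6 rose and 5 fell, at 24 h 6 rose and 2 fell, and at 48 h 6 rose and 9 fell (7 and 5, 8 and 3, and 6 and 9 adjusted over the list alone). The list did not pass its test at any time (medians -0.03, 0.00 and -0.48, adjusted p = 0.71, 0.27 and 0.46). Under scaling by library totals alone the medians were -0.09, -0.07 and -0.76, with 5 higher and 3 lower at 24 h and 5 and 12 at 48 h. At 4 h the median lay below 0 while the test pointed up. MYC rose 6.51-fold at 48 h, from 71.4 ± 5.21 to 465 ± 1.26 CPM (log2 change 2.70, SE 0.07), beside HES1. ID1 rose at 4 h (0.82, SE 0.09) and 24 h before it fell at 48 h. ALDH1A3, an aldehyde dehydrogenase gene, rose at 4 h (0.44, SE 0.06) and was lower at 24 h (-0.53, SE 0.06) and 48 h (-1.37, SE 0.06). MELK, a kinase of dividing cells, fell at 4 h (-1.08, SE 0.11) and rose at 24 h (1.16, SE 0.10), when EZH2 rose by 1.18 (SE 0.08).

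Markers of other cell types were measured too. No count was listed for mitochondrially encoded genes, and erythroid genes reached 0.162 CPM. The highest epithelial marker was KRT8 at 10.8 CPM, the highest endothelial marker KDR at 18.8 CPM and the highest neuronal marker SNAP25 at 39.6 CPM, scaled by library totals. CNP reached 104 CPM among oligodendrocyte markers and GJA1 417 CPM among astrocyte markers. CSF1R, a macrophage receptor gene, was the highest immune marker, at 232 ± 9.84 CPM in control and 330 ± 10.0 CPM at 48 h (log2 change 0.51, SE 0.06). None of these lists except the neuronal one had enough measured members for a list test, and neuronal markers did not pass it (adjusted p = 0.82, 0.95 and 0.70). At 48 h, 3 of 5 neuronal markers were lower and 1 higher (median log2 change -1.03), and 3 of 4 astrocyte markers were lower and 1 higher (median -2.02), with equal counts adjusted over the list alone.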

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

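The differences between times in this part were picked by 1 rule: a gene named in the report's selection, or a list, was called in opposite directions against control at neighbouring times, and the difference between those times passed its own test. The 4 h rise of 6 genes and the 48 h excess of falls were picked apart from that rule, after the results were seen. The minimum difference of 2 log2 units for genes, and every test of an explanation in this part, were chosen after the results were seen.

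Between 4 h and 24 h, 3 lists went from lower to higher than control, with median log2 differences of 2.11 for mitosis, 1.24 for replication and G1/S, and 1.49 for DNA repair. With an estimated correlation none of the 3 passed (adjusted p = 0.17 for each difference, and 0.18 for each list against control at both times). With 4 residual degrees of freedom that form of the test has little power, so these misses do not decide whether the lists shifted. Among genes the same course was taken by E2F2 (log2 difference 3.39), E2F8 (3.17), SPC24 (2.86), AURKB (2.83), EFHC2 (2.61), RRM2 (2.57), ANLN (2.44), TOP2A (2.37), KIF11 (2.28), OAS3 (2.28), MELK (2.24), TPX2 (2.15) and FANCD2 (2.14). KRTAP1-5 went from higher to lower (-3.09). In all, 514 genes went from lower to higher and 197 from higher to lower with the difference past the test. These were all the genes called in opposite directions at 4 h and 24 h. The test of the difference removed none, since opposite calls against the same control nearly imply it.

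Between 24 h and 48 h the ATF4 targets went from lower to higher (median log2 difference 0.85) and the TGF-beta and BMP targets from higher to lower (-0.94). Neither difference passed with an estimated correlation (adjusted p = 0.50 for each). The 24 h calls of both rested on single libraries. The adjusted p of the ATF4 targets at 24 h was 0.35 without control replicate 1 and 0.085 without 24 h replicate 1, and that of the TGF-beta and BMP targets 0.052 and 0.055. LTF (5.87), ADM (3.3), PER1 (3) and OSGIN1 (2.1) went from lower to higher. E2F2 (-5.31), ANGPTL4 (-4.83), CCNE2 (-4.21), E2F8 (-4.13), UHRF1 (-3.7), ID1 (-3.58), SLC16A3 (-2.79), LIF (-2.52), THBS1 (-2.43) and COL5A1 (-2.38) went from higher to lower.

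The mitosis genes were lower than control at 4 h and higher at 24 h. Transcript length and GC content are argued against as the whole cause, since the median difference between 24 h and 4 h was 2.05 with their trend removed. The labels give 0 untreated libraries with a matching time, so medium, handling or time in culture cannot be told apart from the drug. A change in the share of dividing cells under enzalutamide may contribute as well, and was not tested.

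MT1G, MT1M, MT1X, MT1F, SLC30A1 and HMOX1 were higher at 4 h, and they were grouped after their rises were seen, with no test of them as a list. If MT1G and MT1X had only 1 shared source of reads, they would move together, but their log2 changes from 4 h to 24 h differed by 2.11 (SE 0.24); sharing among the other copies stays open. Metal or oxidative stress from the drug may contribute and was not tested, and with 0 time-matched untreated libraries, medium or handling cannot be told apart from it.

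At 48 h more genes fell than rose by at least 2-fold. There were 2290 such falls and 766 rises, 2250 and 799 with DESeq2 size factors and 3185 and 408 with library totals alone, and an effect of scaling stays open. The 48 h change also went with level, with medians of -0.63 and 0.35 in the lowest and highest of 10 equal groups. The 48 h libraries had 16913 and 17009 genes with a count, against 17610 to 17986 in the others. Their 10 most abundant genes held 7.11 and 6.71% of counts, against 4.92 to 5.78%. Whether these features share a cause with the excess of falls was not tested. With transcript length and GC content corrected the ratio of falls to rises was 2.91, which argues against length and GC content as the whole cause. An effect of 48 h of enzalutamide may underlie it, as a hypothesis, and the lack of a time-matched control leaves time in culture open.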

How the results depend on the processing

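Alternatives with library totals, length and GC content, thinning, fits without the 48 h libraries and DESeq2 size factors for the list tests were chosen after seeing the data; the others were planned. No named gene or list past its test turned its direction. The balance of calls turned at 4 h with library totals (1652 higher and 2667 lower), no filter (2030 and 2120) and DESeq2 (1854 and 1879), and at 24 h with library totals (1359 and 1921). Between 24 h and 4 h it turned with DESeq2 size factors (2848 and 3150), DESeq2 (2655 and 2691) and without the 48 h libraries (3465 and 3903), and between 48 h and 24 h with those size factors (4840 and 4833) and DESeq2 (4676 and 4423). At 48 h it was near even and turned with those size factors (4929 and 4759), no filter (4846 and 4830), DESeq2 (4738 and 4375) and the replicate block, and when some single libraries were left out. Library totals turned the medians of some lists that did not pass, among them the androgen and xenobiotic lists at 48 h (-0.20 and -0.18). The length and GC correction also turned some of these, such as the histones at 48 h (-0.04). Over all alternatives, calls of named genes were kept in 5318 cases and lost in 62, and list results were kept in 484 cases, lost in 38 and gained in 8. Where a value moved, the cause was not tested, except that a fold minimum can only lower a count. With a log2 change of at least 1, the counts were 353 higher and 236 lower at 4 h, 244 and 171 at 24 h, 766 and 2290 at 48 h, 1149 between 24 h and 4 h and 3128 between 48 h and 24 h. With library totals as the only scaling 2742 genes were higher at 48 h. The count lower at 24 h was 2413 in a fit of only the 2 groups and 2330 without the 48 h libraries. Lists past the test numbered 12, 10 and 8 at 4, 24 and 48 h. With camera's estimated correlation they numbered 0, 0 and 0. Of 32 lists, 8, 5 and 1 then had an unadjusted p under 0.05, in a test with only 4 residual degrees of freedom. Fry gave 19, 13 and 27. By fry, which does not compare a list with other genes, the androgen list passed at 4, 24 and 48 h (adjusted p = 0.0042, 0.0021 and 0.032), as did the glioma stem cell list (0.026, 0.0048 and 0.00026). The ATF4 targets and the TGF-beta and BMP targets at 24 h did not pass by fry (adjusted p = 0.19 and 0.054).

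Leaving out each library in turn gave 1207 to 2992 genes higher and 986 to 2791 lower at 4 h, 843 to 2879 and 489 to 2075 at 24 h, and 4146 to 5016 and 4115 to 4828 at 48 h. Between 24 h and 4 h it gave 3823 to 7338, and between 48 h and 24 h 8273 to 9811. Lists numbered 12 to 14, 8 to 13 and 8 to 10.

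The replicate numbers showed at most a weak pairing of the libraries. Deviations from the group means correlated at -0.005 to 0.135 across genes for the 6 pairs of groups, and a small shared replicate effect is not excluded. With the replicate number as a block, 2411 genes were higher and 2213 lower at 4 h, 2169 and 1580 at 24 h, and 4945 and 4939 at 48 h, and no list or named gene call changed. Each of these counts was larger than without the block. Genes below the filter on low counts were not tested in the reported fit and entered only some of the other settings.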

Other observations

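The test of exon number in this part was set down before its result was seen, and the groupings by exon number and level were described after.

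Lists that did not pass their test at any time still held called members. Of all tested genes, 28.6% were called at 4 h, 22.3% at 24 h and 66.9% at 48 h. Among BCL2 family genes 4 of 14 rose and 2 fell at 4 h, and 8 rose and 2 fell at 48 h (8 and 4 adjusted over the list alone, median log2 change 0.28, adjusted p = 0.33). Mesenchymal genes rose in 12 of 20 cases and fell in 5 at 48 h (median 0.29, adjusted p = 0.15), with SNAI2 at 2.20 (SE 0.07) and VIM at 0.71 (SE 0.05). All 4 called hedgehog genes of the 5 measured fell at 48 h (median -1.37, adjusted p = 0.056), among them PTCH1 (-1.84, SE 0.18), GLI2 (-1.37, SE 0.10) and BOC (-1.19, SE 0.18). YAP targets rose in 2 of 10 cases and fell in 6 at 48 h (median -0.61, adjusted p = 0.20).

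Notch targets rose in 2 of 5 cases and fell in 1 at 48 h (median -0.15, mean 0.76, adjusted p = 0.76), Wnt targets rose in 1 of 8 and fell in 3 (median -0.55, adjusted p = 0.40), and fatty acid synthesis genes rose in 6 of 13 and fell in 5 (median 0.36, adjusted p = 0.84). Steroid receptors and enzymes rose in 1 of 14 cases and fell in 5 (median -0.08, adjusted p = 0.67), xenobiotic genes rose in 4 of 8 and fell in 3 (median 0.10, or -0.18 with library totals as the only scaling, adjusted p = 0.91), and replication histones, which share reads among copies, rose in 4 of 12 and fell in 2 (median 0.30, or -0.04 with transcript length and GC content corrected, adjusted p = 0.84). Under scaling by library totals alone, the 48 h counts of higher and lower genes were 4 and 6 for the BCL2 family (median 0.00, or 0.06 with length and GC content corrected), 3 and 6 for fatty acid synthesis (median 0.09), 1 and 7 for steroid receptors and enzymes (median -0.36), 2 and 2 for Notch targets (median -0.43), 0 and 5 for Wnt targets (median -0.82), 1 and 7 for YAP targets (median -0.89), 2 and 4 for xenobiotic genes, 1 and 2 for histones (median 0.02) and 8 and 6 for mesenchymal genes (median 0.01). Higher and lower BCL2 family genes at 4 h were then 3 and 3. Of the steroid receptors and enzymes, 3 were higher and 5 lower at 48 h with DESeq2 size factors, and 4 and 5 with transcript length and GC content corrected. At 4 h the numbers higher and lower were 3 and 0 for Notch targets (median 0.73, adjusted p = 0.078), 3 and 1 for YAP targets (-0.03), 2 and 1 for Wnt targets (-0.17), 1 and 1 for hedgehog genes (-0.11), 4 and 1 for fatty acid synthesis (0.19), 1 and 3 for steroid receptors and enzymes (-0.17), 4 and 1 for xenobiotic genes (0.48), 1 and 0 for histones (0.15) and 7 and 6 for mesenchymal genes (0.01, or -0.05 with library totals). At 24 h they were 0 and 1 (0.18, or -0.01 with transcript length and GC content corrected), 3 and 0 (-0.06), 1 and 1 (0.18), 0 and 0 (-0.33), 2 and 2 (0.14), 1 and 1 (-0.02), 0 and 3 (-0.14), 0 and 1 (-0.35) and 6 and 1 (0.16) in the same order, and 0 and 1 for the BCL2 family (0.11). The median and the test differed in sign for Wnt targets, hedgehog genes and the BCL2 family at 4 h, Notch targets and the BCL2 family at 24 h, YAP targets at both times, and Notch targets at 48 h. Counts adjusted over the list alone differed at 4 h for YAP targets (3 and 3), fatty acid synthesis (5 and 1), steroid receptors and enzymes (3 and 4), xenobiotic genes (6 and 1), histones (0 and 0) and the BCL2 family (4 and 3), and at 24 h for Notch targets (1 and 1), Wnt targets (2 and 2), xenobiotic genes (2 and 3), mesenchymal genes (8 and 2) and the BCL2 family (0 and 0). Adjusted over the list alone, the 48 h counts of these lists were equal to those over all genes, except for 1 and 2 Wnt targets, 4 and 4 xenobiotic genes and the BCL2 family above.

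Genes whose annotated transcripts have 1 or 2 exons were lower at 48 h, with a median log2 change of -0.38 over 847 genes, 374 of them called lower and 207 higher. Medians were -0.05 for genes with 3 to 5 exons, 0.07 for 6 to 10, 0.04 for 11 to 20 and -0.09 for 21 or more, the last with 665 genes lower and 521 higher. For genes with 1 or 2 exons the median was 0.05 at 4 h (145 called higher and 89 lower) and -0.07 at 24 h (49 and 96). Lower abundance and transcript length are argued against as the whole cause of the 48 h fall, since the central 95% of 10000 sets of genes with more exons, matched on both, had medians from -0.24 to -0.10. Matching used 10 bins of mean level over all libraries and 5 bins of length, so differences within bins stay possible. A bin short of genes with more exons could give fewer of them. Shorter-lived transcripts are a candidate explanation that was not tested, and genes are not independent replicates.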
